A study of Oryctolagus cuniculus with 16 samples.

How the data were processed

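RNA was extracted from microglia and O4-positive OPC sorted at day 7 from rabbit kits with intraventricular haemorrhage, and was sequenced as paired-end reads on an Illumina instrument by a commercial provider, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b and Subread 1.5.2 without saying what each did. The deposited values are whole-number read counts per gene, 1 file per library, not normalized. Per the file headers, each gene has an Ensembl rabbit identifier, exon positions, strand and length, in the layout of Subread's counting program. The genome build, the annotation release and whether counting used strand are not given in the sources used here, so coordinates are as the files give them, and reads of overlapping, antisense or near-identical genes may have been split or lost between them. Every file lists the same 23669 genes, all with an identifier.

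The reference table given with the series lists 38822 genes of the rabbit assembly mOryCun1.1, and 0 of the files' identifiers matched it. Gene names could therefore not be attached. The 32 gene lists fixed before the data were examined (21 pathway and 11 cell-type marker lists), the level of PPARg itself and the rule's requirement of a gene symbol could not be used. Classes of genes that need no names were compared in their place, all defined after the files were seen: microglia-enriched and OPC-enriched genes, mitochondrial genes of at least 200 bp upstream and downstream of position 7000, X-linked genes, and single-exon genes shorter and longer than 300 bp. Cell-type-enriched genes were those with an edgeR adjusted p under 0.05 and a difference of at least 16-fold between the sorts. Haemoglobin and ribosomal RNA genes could not be picked out, so that only mitochondrial genes were left out in the setting planned for all 3.

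Samples were grouped by the cell type and treatment in their labels, 4 libraries in each of 4 groups. Treatment was compared within each cell type in its own fit of 8 libraries, and the difference of the effects was tested in a fit of all 16. The comparison of the 2 sorts was added after the files were seen. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fits) on the deposited counts, with TMM scaling, edgeR's default filter on low counts and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was taken as its size divided by the square root of F. CPM are counts relative to library totals scaled by TMM, except in the account of the mitochondrial genes, which uses raw totals. Classes were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 7 classes of a comparison, with an estimated correlation and fry beside it. Log2 CPM for correlations between libraries used a prior count of 2. Library measures were compared by two-sided exact permutation of 4 against 4, whose smallest p is 0.0286.

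By the rule fixed beforehand, fewer than 10 genes passed in each treatment comparison, so the 10 lowest in p were taken instead and are reported as not past the threshold. Without names, 2 identifiers per direction are printed for each treatment comparison and none for the difference of effects. Numbers of "exon entries" count the annotated exon records of a gene over all its transcripts.

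Each library of a group came from a different animal by the identifiers in the labels. The 24 pairs of libraries within groups differed by 6.75 to 234 chi-square units per gene, where sampling noise gives about 1, so no library was counted as a repeat of another. The identifiers also pair the cell types: in the 6 animals with both, deviations from the group means correlated at 0.0708 to 0.357 across 9484 genes (median 0.254). The median was -0.110 (-0.502 to 0.493) for other animals of the same treatment and -0.0053 (-0.319 to 0.349) for animals of the other treatment. Taking out group means by itself lowers the values between different animals of 1 treatment. The ranges overlap, and 4 of the 6 microglia libraries correlated best with the OPC library of their own animal. The first part of the identifier takes 6 values, 3 per treatment and none in both, and the labels do not say what it stands for. In OPC, the Ad-PPARg libraries cover all 3 of theirs and the Ad-GFP libraries fewer than 3.

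Totals of 6.24 to 17.6 M (mega) counts limit single values little: the 95% Wilson interval of the share on short genes in microglia Ad-PPARg replicate 1 is 4.47 to 4.51%. Such intervals cover counting error only, and the spread between animals is far wider. The fits of the treatment comparisons and of the difference of effects were tested on simulated data drawn from the real means, totals and dispersions. In these, 100 genes were changed by 2-fold and 100 by 4-fold, all with a mean log2 CPM above 2. The recovery given here holds for such genes only. Block, summed and covariate fits and the comparison of the sorts were not simulated. For microglia (13041 genes), edgeR recovered 66% of the 2-fold and 94% of the 4-fold changes with 6 false calls, and DESeq2 80% and 97% with 43 false calls. For OPC (13492 genes), edgeR recovered 26% and 88% with 8 false calls, and DESeq2 53% and 95% with 41. For the difference of effects (14699 genes), edgeR recovered 5% and 63% with 3 false calls, and DESeq2 28% and 78% with 30. Limma voom with sample quality weights recovered 63% and 95% in microglia (6 false calls) and 28% and 88% in OPC (9). For the difference of effects it recovered 5% and 61% (1 false call). The simulation had no shared litters or other structure among libraries.

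Alternatives fixed beforehand were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom with sample quality weights, an added 2-fold threshold, mitochondrial genes left out, each library left out in turn, all 16 libraries in one fit, the identifier prefix as a random block or summed to 1 library, and the animal as a fixed or random block. Fits with the mitochondrial split as a covariate, within the libraries that express the block, without both first replicates, and with limma voom with neither block nor weights were added after seeing the data.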

Results

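The series holds RNA-seq of cells sorted from the cerebral hemispheres of premature New Zealand rabbit kits with intraventricular haemorrhage, the bleeding into the brain's ventricles that affects preterm newborns. Kits received an adenovirus into the ventricle that carried either PPARg together with green fluorescent protein (Ad-PPARg) or green fluorescent protein alone (Ad-GFP). PPARg is a ligand-activated nuclear receptor that regulates lipid metabolism and inflammatory genes, and Ad-GFP is the vector control. At day 7, microglia (CD11b-positive cells with low CD45, the resident immune cells of the brain) and O4-positive oligodendrocyte progenitor cells (OPC, the precursors of the cells that make myelin) were sorted by flow cytometry. Each cell type was sequenced from 4 Ad-PPARg and 4 Ad-GFP animals, 16 libraries in all. The libraries came from 10 animals, and 6 of these, 3 per treatment, gave both cell types. Total counts on genes were 6.24 to 14.9 M in the microglia Ad-PPARg libraries, 6.64 to 17.6 M in the microglia Ad-GFP libraries, 11.8 to 14.3 M in the OPC Ad-PPARg libraries and 6.56 to 15.8 M in the OPC Ad-GFP libraries. Totals did not differ between treatments by more than the spread between animals in microglia (11.9 ± 3.93 M against 13.4 ± 4.81 M, mean ± SD, n = 4 each, two-sided exact permutation p = 0.571) or in OPC (12.8 ± 1.07 M against 11.0 ± 4.03 M, n = 4 each, exact permutation p = 0.457). Genes are identified in the deposited files by Ensembl rabbit identifiers and positions only. The files do not pair these with names, and the PPARg gene itself was therefore not examined here.

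The 2 sorts were compared first, as a check of what the libraries contain. Microglia and OPC had widely different transcriptomes: of 14699 genes tested over all 16 libraries, 5156 were higher in OPC and 4915 higher in microglia (edgeR, adjusted p under 0.05), and 3368 and 3094 of these differed by at least 2-fold. The strongest contrasts, at least 16-fold, defined 828 microglia-enriched and 742 OPC-enriched genes. Microglia-enriched genes took up 24.5% ± 1.59 of the counts in microglia libraries (SD, n = 8, range 21.4 to 26.7%) and 0.801% ± 0.210 in OPC libraries (n = 8, range 0.575 to 1.18%). OPC-enriched genes took up 13.4% ± 1.64 of the counts in OPC libraries (n = 8, range 11.9 to 16.9%) and 0.273% ± 0.116 in microglia libraries (n = 8, range 0.101 to 0.495%). These sets were defined on the same libraries, so the shares describe them and do not test the sorts. Spearman correlations between libraries were 0.946 to 0.989 within microglia, 0.912 to 0.991 within OPC and 0.637 to 0.725 between the cell types. Upper-quartile scaling changed the numbers to 6132 higher in OPC and 4232 higher in microglia, and moved the median log2 difference of all genes from -0.0097 to 0.19.

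**Figure D1:**
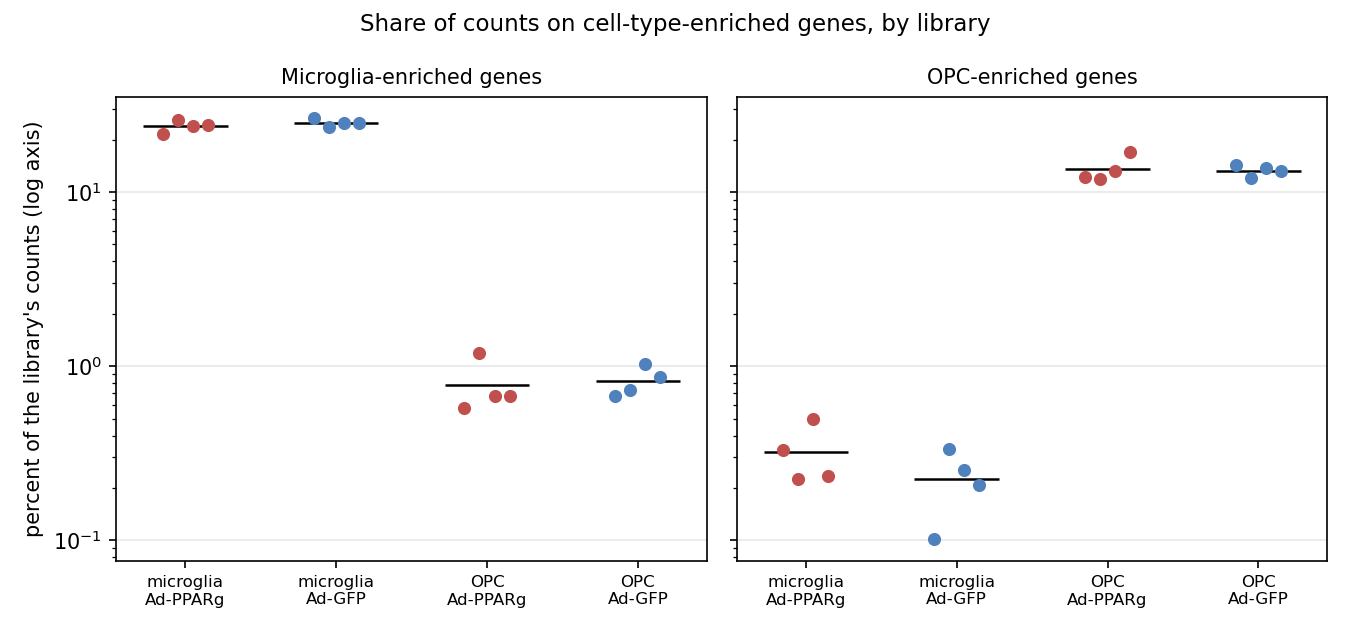
Percent of each library's counts on the 828 microglia-enriched genes (left) and the 742 OPC-enriched genes (right), on a log axis, for the 4 groups; points are libraries and bars are the means of 4 libraries. Microglia libraries lie between 21.4 and 26.7% for microglia-enriched genes and OPC libraries between 11.9 and 16.9% for OPC-enriched genes.

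The share of counts on the sort-enriched genes did not separate the treatments. In microglia, microglia-enriched genes held 23.9% ± 1.85 of the counts after Ad-PPARg and 25.02% ± 1.29 after Ad-GFP (SD, n = 4 each, exact permutation p = 0.4), and OPC-enriched genes held 0.321% ± 0.125 and 0.225% ± 0.0980 (n = 4 each, exact permutation p = 0.343). In OPC, OPC-enriched genes held 13.5% ± 2.30 and 13.3% ± 0.959 (n = 4 each, exact permutation p = 0.943), and microglia-enriched genes 0.778% ± 0.275 and 0.824% ± 0.159 (n = 4 each, exact permutation p = 0.8). Of 14 such library measures compared between treatments, only the mitochondrial share in OPC reached the smallest p that 4 against 4 allows. It was 2.16% ± 0.660 after Ad-PPARg and 3.09% ± 0.217 after Ad-GFP (n = 4 each, two-sided exact permutation p = 0.0286, 0.4 after Benjamini-Hochberg adjustment over the 14), and in Ad-PPARg replicates 1 and 4 a block of mitochondrial genes was near 0. In microglia it was 1.82% ± 0.669 and 2.67% ± 1.21 (n = 4 each, exact permutation p = 0.257). These permutations take the libraries as exchangeable, although some come from animals that share the first part of their identifier.

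The first comparison the design names asks how PPARg overexpression changed the microglial transcriptome. No single microglial gene passed the adjusted threshold. The 4 genes with the lowest p, 2 lower and 2 higher after Ad-PPARg, differed by 3.32-fold to 11.4-fold, and the 4 libraries of 1 treatment did not overlap the 4 of the other in any of them. ENSOCUG00000029263 (chromosome 14, 53115895 to 53176541, minus strand, 6 annotated exon entries) was at 5.17 ± 1.39 CPM after Ad-PPARg against 26.9 ± 8.14 after Ad-GFP (SD, n = 4 each), a log2 fold change of -2.38 (SE 0.27, edgeR adjusted p = 0.0890). ENSOCUG00000013247 (chromosome 14, 87023626 to 87023994, minus strand, a single exon) was at 0.819 ± 0.485 against 9.61 ± 5.00 CPM (n = 4 each), a log2 fold change of -3.51 (SE 0.50, edgeR adjusted p = 0.142). ENSOCUG00000026015 (chromosome 5, 22586307 to 22596405, plus strand, 13 exon entries) was at 35.9 ± 7.15 against 10.9 ± 3.32 CPM (n = 4 each), a log2 fold change of 1.73 (SE 0.24, edgeR adjusted p = 0.142). ENSOCUG00000002957 (chromosome 13, 43153367 to 43168379, minus strand, 2 exon entries) was at 30.6 ± 1.89 against 6.92 ± 3.87 CPM (n = 4 each), a log2 fold change of 2.18 (SE 0.31, edgeR adjusted p = 0.142).

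Among the 10 genes with the lowest p in microglia, 5 were higher and 5 lower after Ad-PPARg. In all 10, the 4 above included, the CPM ranges of the treatments did not overlap. Genes picked for a low p tend to be separated in this way, so this adds no support. The same held for the 10 genes with the lowest p in OPC. The annotated neighbour 3200 bp upstream of ENSOCUG00000026015 on chromosome 5 (22576123 to 22583107, same strand) was also among these 10, at 23.2 ± 4.49 against 7.79 ± 3.07 CPM (SD, n = 4 each), 3.01-fold higher. Of 13041 genes tested with edgeR, 0 had an adjusted p under 0.05, and 1488 (11.4%) had an unadjusted p under 0.05, where evenly spread p-values would give 652. At least as many were found in 5 of the 35 divisions of these 8 libraries into 4 and 4, the real one included. Of the 1488, 635 were higher and 853 lower after Ad-PPARg. The treatments did not overlap in 541 genes (4.15%), 240 higher and 301 lower, where chance gives 2.86%. That chance value takes the libraries as exchangeable, although some come from animals that share an identifier prefix. The median SE of a log2 fold change was 0.20. DESeq2 called 100 genes (48 higher, 52 lower) and limma voom with sample quality weights called 1291 (646 higher, 645 lower). The unadjusted count moved when single libraries were left out: it was 735 without Ad-PPARg replicate 3, 819 without Ad-GFP replicate 3, 984 without Ad-GFP replicate 1 and 2801 without Ad-GFP replicate 4. Without each of the other 4 in turn it was 1044 to 1668. Each of these fits also has fewer libraries. Animals that share the first part of their identifier, the prefix, all received the same treatment. No prefix shows both treatments, so the treatment can be judged only against the spread between prefixes, 3 per treatment. With counts summed per prefix, edgeR called 0 genes and 524 had an unadjusted p under 0.05. With the prefix as a random block, limma voom called 1 gene and 808 had an unadjusted p under 0.05.

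**Figure D2:**
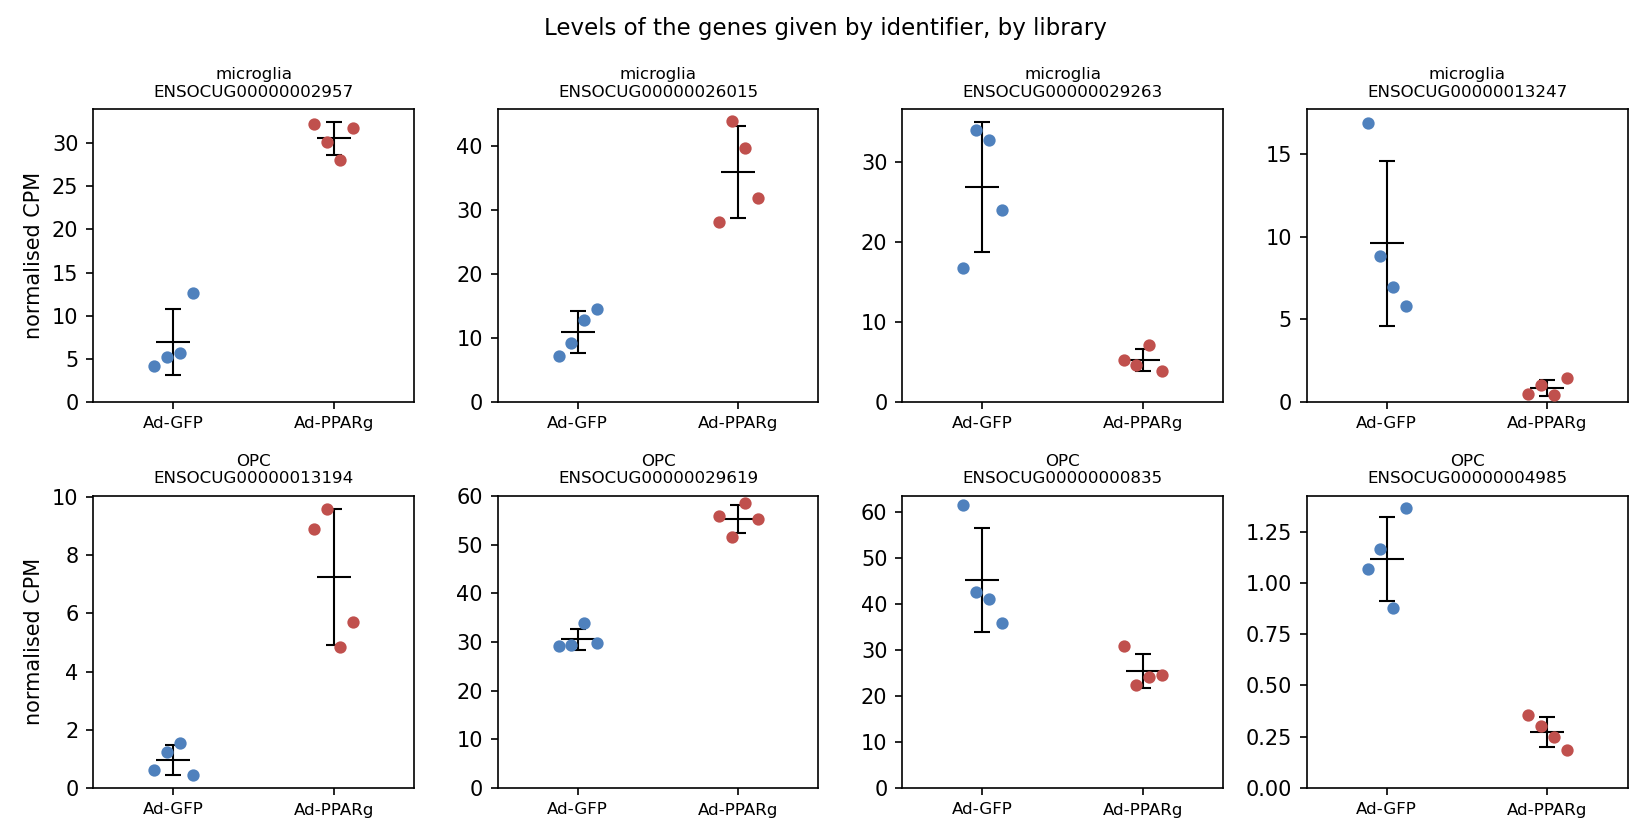
Normalised CPM in each library (points), with mean and SD of 4 libraries (bars), for the genes given by identifier in microglia (upper panels) and OPC (lower panels); every axis starts at 0. Points of the treatments do not overlap in any panel, and none of these genes had an edgeR adjusted p under 0.05. The genes were picked for a low p in these libraries, so their separation is not a separate test.

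Classes of genes were compared in microglia in place of the planned gene lists, and were defined only after the files had been seen. OPC-enriched genes lay higher after Ad-PPARg in microglia: 469 of 524 tested had a positive log2 fold change, with a median of 0.47 (camera adjusted p = 1.01e-06 with a preset correlation, adjusted p = 0.880 with an estimated correlation). The mean level of the class did not separate the animals (exact permutation p = 0.457, n = 4 each), and no member passed the threshold, either over all genes or adjusted over the list alone. The camera call was absent without Ad-PPARg replicate 3, the microglia library with the highest share on OPC-enriched genes (0.495%), and without Ad-GFP replicate 1, the one with the lowest (0.101%). Microglia-enriched genes went both ways, 442 higher and 386 lower of 828, with a median log2 fold change of 0.042 (camera adjusted p = 0.471), and 2 of them passed when adjusted over the list alone, both higher. Of the 5 mitochondrial genes upstream of position 7000, 2 passed when adjusted over the list alone, both lower. That class had 2 higher and 3 lower members, a median log2 fold change of -0.42 and a mean of 0.16 (camera direction down, adjusted p = 0.0794, and 0.880 with an estimated correlation). All 10 mitochondrial genes downstream of position 7000 had lower fitted levels, with a median log2 fold change of -1.16 (camera adjusted p = 0.0794). These genes summed to only 85.9 and 50.9 CPM in Ad-PPARg replicates 1 and 2 and 78.1 CPM in Ad-GFP replicate 1. In the other microglia libraries they summed to 8696 to 19476 CPM. Their mean level did not separate the animals (exact permutation p = 0.257, n = 4 each). X-linked genes (169 of 366 higher) and longer single-exon genes (327 higher, 326 lower of 653) did not pass the class test, and 1 longer single-exon gene passed when adjusted over the list alone, lower. Short single-exon genes, under 300 bp, were higher in 117 and lower in 80 (camera adjusted p = 0.909).

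The second comparison asks the same of OPC. No OPC gene passed the adjusted threshold. The 2 genes with the lowest p were both higher after Ad-PPARg. ENSOCUG00000029619 (scaffold AAGW02081638, 14710 to 23433, minus strand, 4 exon entries) was at 55.3 ± 2.87 CPM against 30.5 ± 2.20 (SD, n = 4 each), a log2 fold change of 0.86 (SE 0.12, edgeR adjusted p = 0.608). ENSOCUG00000013194 (chromosome 9, 11495298 to 11632637, minus strand, 8 exon entries) was at 7.26 ± 2.34 against 0.964 ± 0.507 CPM (n = 4 each), a log2 fold change of 2.89 (SE 0.44, edgeR adjusted p = 0.608). Lowest in p among the genes with lower levels were ENSOCUG00000004985 (scaffold GL018831, 243155 to 245448, minus strand, 6 exon entries), with a log2 fold change of -1.97 (SE 0.41) and only 2 to 17 counts per library, and ENSOCUG00000000835 (chromosome 2, 113501398 to 113506619, minus strand, 3 exon entries), at 25.5 ± 3.66 against 45.3 ± 11.3 CPM (n = 4 each), with a log2 fold change of -0.83 (SE 0.20). Both had an edgeR adjusted p of 1.00.

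Of 13492 genes tested in OPC with edgeR, 0 had an adjusted p under 0.05 and 166 had an unadjusted p under 0.05 (103 higher, 63 lower), where evenly spread p-values would give 675. The treatments did not overlap in 169 genes (1.25%), below the 2.86% that chance gives if the libraries are taken as exchangeable. As in microglia, no prefix shows both treatments, and here Ad-GFP covers fewer prefixes than Ad-PPARg. DESeq2 called 7 genes, all higher after Ad-PPARg, and limma voom with sample quality weights called 9. The median SE of a log2 fold change was 0.25, against 0.20 in microglia. One library stood apart from the others: Ad-PPARg replicate 4 had a median Spearman correlation of 0.941 with the other OPC libraries, whose own values were 0.971 to 0.987, and held the highest share on OPC-enriched genes (16.9%, against 11.9 to 14.2% in the other 7). Without it, edgeR called 2 genes, both lower, and the unadjusted count was 1051; without Ad-PPARg replicate 2 that count was 328.

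Among the classes in OPC, short single-exon genes lay higher after Ad-PPARg (208 of 267, median log2 fold change 0.32, camera adjusted p = 4.67e-09), and this call did not hold with an estimated correlation (adjusted p = 0.275). The mean log2 level of the class was 1.97 ± 0.37 after Ad-PPARg and 1.74 ± 0.080 after Ad-GFP (SD, n = 4 each, exact permutation p = 0.2), and Ad-PPARg replicate 1 had the highest share of counts on short genes (1.43%, against 0.685 to 0.833% in the other 7). Microglia-enriched genes lay lower (372 of 566, median -0.14, camera adjusted p = 3.93e-05), again not with an estimated correlation (adjusted p = 0.627), and their mean level did not separate the animals (exact permutation p = 0.571, n = 4 each). OPC-enriched genes were called lower by camera (adjusted p = 0.000830, and 0.275 with an estimated correlation) with a median log2 fold change of -0.0043 and a mean of 0.031 over 355 higher and 387 lower members of 742 (exact permutation p of the mean level = 0.229, n = 4 each). The 10 mitochondrial genes downstream of position 7000 all lay lower (median -1.29, camera adjusted p = 3.44e-15, and 0.252 with an estimated correlation). The difference came mainly from Ad-PPARg replicates 1 and 4, where these genes summed to 107 and 80.0 CPM, against 13659 and 14227 CPM in replicates 2 and 3 and 15025 to 18179 CPM after Ad-GFP. The mean log2 level of the class was 6.22 ± 4.27 after Ad-PPARg and 10.22 ± 0.14 after Ad-GFP (SD, n = 4 each, exact permutation p = 0.0286, the smallest that the design allows). This permutation takes the libraries as exchangeable, although some come from animals that share an identifier prefix. All animals of a prefix were alike in this block, so the permutation overstates the separation of the treatments. The 5 mitochondrial genes upstream of position 7000 did not pass (3 higher, 2 lower, median 0.028, mean 0.027, camera direction down, adjusted p = 0.457). X-linked genes (199 higher, 203 lower of 402) and longer single-exon genes (365 higher, 322 lower of 687) did not pass.

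The difference of the treatment effect between the cell types was tested directly over all 16 libraries. No gene passed: of 14699 tested with edgeR, 0 had an adjusted p under 0.05, the lowest adjusted p was 0.997, and 402 had an unadjusted p under 0.05 where evenly spread p-values would give 735. DESeq2 called 2 genes and limma voom with sample quality weights called 4. The unadjusted count was 239 without microglia Ad-PPARg replicate 3, 613 without microglia Ad-PPARg replicate 2, 881 without microglia Ad-GFP replicate 4, 792 without OPC Ad-PPARg replicate 2 and 910 without OPC Ad-PPARg replicate 4. ENSOCUG00000029263, with a log2 fold change of -2.38 in microglia, was at -0.14 (SE 0.49) in OPC, and the difference of 2.20 (SE 0.57) had an edgeR adjusted p of 0.997. ENSOCUG00000013194, with a log2 fold change of 2.89 in OPC, was at 0.56 (SE 0.21) in microglia, and the difference of 2.29 (SE 0.44) had an edgeR adjusted p of 0.997. ENSOCUG00000026015 and ENSOCUG00000002957 were too low in OPC to be tested there alone. In the fit of all 16 libraries their differences were -2.37 (SE 0.69) and -1.73 (SE 0.91), each with an edgeR adjusted p of 0.997. The median SE of a difference was 0.39. In simulated data of this size, changes were placed in well-expressed genes only. There, edgeR recovered 5% of genes whose effects differed by 2-fold and 63% of those that differed by 4-fold, with 3 false calls. DESeq2 recovered 28% and 78% with 30 false calls. Differences of 2-fold were thus mostly not detectable here with either tool.

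**Figure D3:**
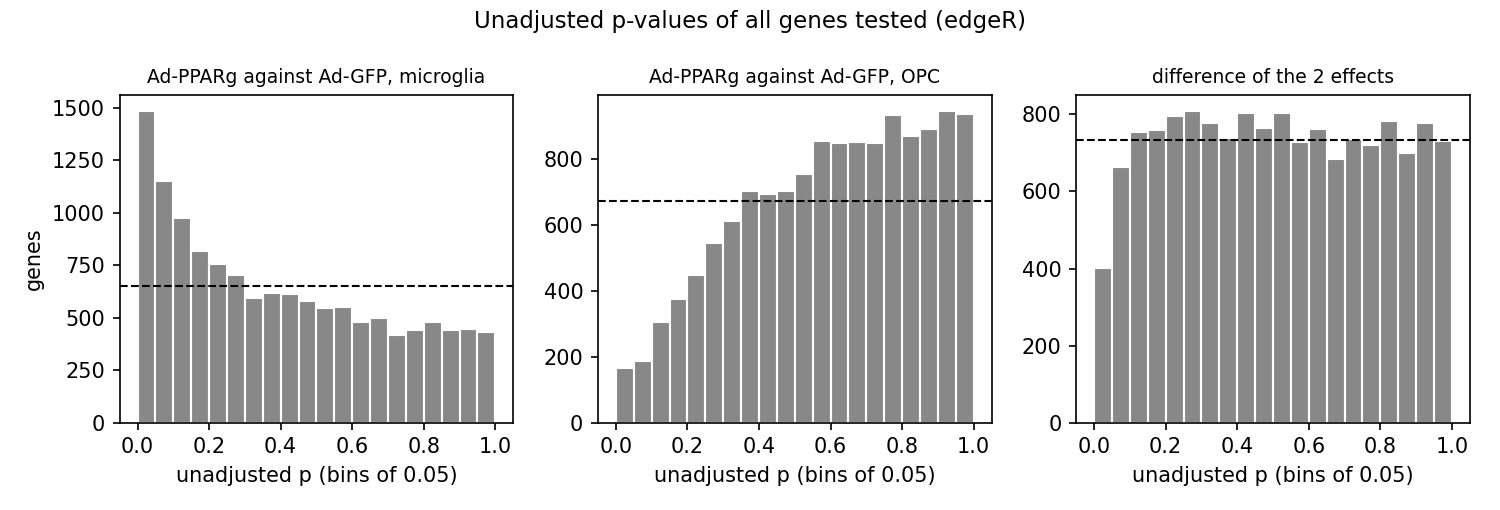
Unadjusted p-values from edgeR for all genes tested in microglia, in OPC and for the difference of the 2 effects, in bins of 0.05; the dashed line is the number per bin that evenly spread p-values would give. The first bin holds 1488 genes in microglia, 166 in OPC and 402 for the difference.

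Mitochondrial transcripts split the libraries in a way that crossed the cell types and was not evenly spread over the treatments. In 5 libraries the 10 mitochondrial genes between positions 7039 and 15313 summed to 50.9 to 107 CPM, and in the other 11 to 8696 to 19476 CPM. The gene at positions 5354 to 6895, just upstream, had a median of 9903 CPM in the 5 and 9737 in the 11. Another upstream gene, of 69 bp at positions 5212 to 5280, did separate them, with medians of 0.606 CPM in the 5 and 14.6 in the 11. On scaffold AAGW02081404, 2 short genes (24130 to 24426 and 27532 to 27689) went the other way, with median levels of 422 and 1584 CPM in the 5 libraries and 2.10 and 5.13 in the 11. The 5 libraries were microglia Ad-PPARg replicates 1 and 2, microglia Ad-GFP replicate 1 and OPC Ad-PPARg replicates 1 and 4. Within the libraries that expressed the block, chosen after seeing the data, edgeR called 57 genes in microglia (23 higher, 34 lower, 2 libraries against 3) and 47 in OPC (30 higher, 17 lower, 2 against 4), and 2 genes were called in both. In both cell types these 2 Ad-PPARg libraries came from the same 2 animals, which share 1 identifier prefix and are treated as independent in each fit. The Ad-GFP animals of the microglia fit were also in the OPC fit. The 2 genes called in both therefore do not come from separate animals. With the split as a covariate in all 8 libraries, edgeR called 91 genes in microglia (46 higher, 45 lower), 26 of them also among the 57, and 1 in OPC.

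**Figure D4:**
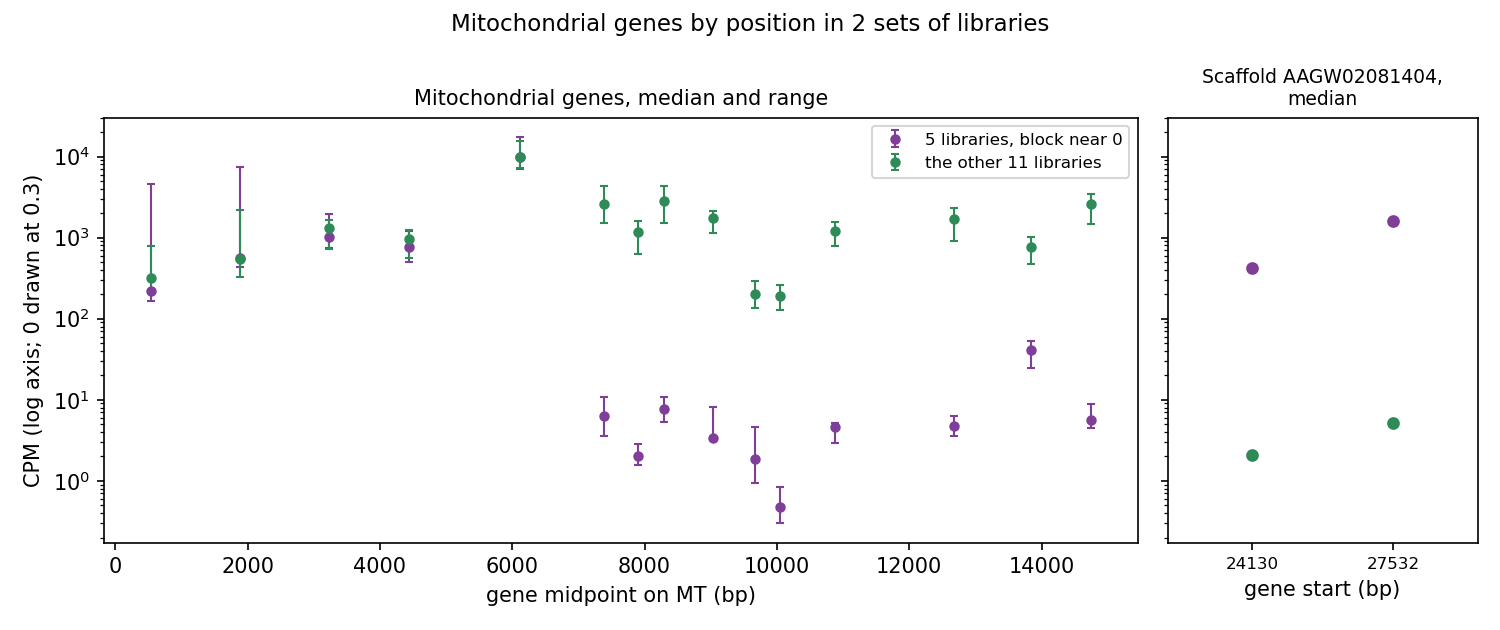
CPM of the mitochondrial genes of at least 200 bp by position (left: median and range over libraries, log axis, a value of 0 drawn at the bottom) and of 2 genes on scaffold AAGW02081404 (right: medians), for the 5 libraries in which the block is near 0 and for the other 11. Of the genes drawn, those upstream of position 7000 overlap, and the 10 downstream do not.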

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

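All explanations weighed in this part were tested only after the result had been seen, and the design gives no group that would test a biological explanation for the library differences described here.

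Of 44 sets of 4 values examined (library measures and the genes given by identifier, per group), 3 held 1 value far from the other 3, where chance gives about 2.2 (1 in 20). Microglia Ad-PPARg replicate 1 had 4.49% of its counts on genes shorter than 300 bp, against 0.823 to 0.981% in the other 3. OPC Ad-PPARg replicate 2 had 1.18% of its counts on microglia-enriched genes, against 0.575 to 0.677% in the other 3 and 0.671 to 1.03% in the OPC Ad-GFP libraries. OPC Ad-GFP replicate 3 had 33.8 CPM of ENSOCUG00000029619, against 29.2 to 29.8, all below the 51.6 to 58.5 of the Ad-PPARg libraries.

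The excess of short genes in microglia Ad-PPARg replicate 1 came mostly from 18 loci of 74 to 153 bp on scaffold GL019111, which held 3.08% of its counts and 0.0389 to 0.118% in the other 7 microglia libraries. A general gain of short RNAs is argued against as the whole cause: the 279 other short single-exon genes tested had a median log2 difference of 0.26 from the other microglia libraries (quartiles -0.33 and 0.82), although the share of short genes outside the scaffold was also the highest of the 8 (1.41%, against at most 1.15%). Depth is argued against as well, since the microglia library with the next lowest total had a share 4.71 times lower. The OPC library of the same animal had 0.213% of its counts on the scaffold genes, the highest of the 8 OPC libraries (0.0235 to 0.107% in the others). A property of the animal may therefore be involved, and this stays open because being the highest of 8 is too frequent by chance.

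The mitochondrial block split the libraries into 5 and 11 with no intermediate. Of 9900 genes examined, 12 separated the 5 from the 11 by at least 10-fold, 10 on the mitochondrial sequence (9 of the block and the upstream gene at 5212 to 5280, without the block's gene at 13579 to 14103), 2 on scaffold AAGW02081404 and 0 elsewhere, where the genes of the block, by which the 5 were picked, do not test the split. Depth is argued against, since the lowest level of the 11 would give 54285 reads at the lowest depth of the 5, and so is a reference without one of the sequences, since every library had at least 50 reads on each. A maternal line with a mitochondrial sequence unlike the reference, whose reads go elsewhere, is a candidate explanation. Both libraries of all 6 animals with 2 cell types were of 1 kind, and so were all animals of each of the 6 identifier prefixes. Of the 210 divisions of the 10 animals into 4 and 6, 4.76% would keep every prefix whole. This agreement is limited, since only 4 of the 6 prefixes hold more than 1 animal. Of the animals with both cell types, only that of replicate 1 in both Ad-PPARg groups had the block near 0. Such a line was not tested on sequence, and under it the split would say nothing of mitochondrial expression.

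OPC Ad-PPARg replicate 4 stood apart from the other 7 OPC libraries, with a median correlation of 0.941 and a place on the far end of the first principal component, which held 58.7% of the variance. RNA from microglia is argued against, since microglia-enriched genes held 0.674% of its counts and up to 1.18% in the others, and so is depth, with 12.4 M counts against 6.56 to 15.8 M. A litter or handling effect may be involved: its deviations correlated at 0.220 with those of the microglia library of the same identifier prefix, the highest of the 8 microglia libraries (-0.20 to 0.123 for the others). This stays open because the highest of 8 is too frequent by chance, and a response of this animal to the vector was not tested.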

How the results depend on the processing

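Fits with the mitochondrial split, within the libraries that express the block or without both first replicates, limma voom with neither block nor weights, the comparison of the sorts and the classes of genes were chosen after seeing the data. The causes of the changes given here were not tested. In microglia, the count of 0 genes became 4 with no low-count filter, 100 with DESeq2, 1291 with sample quality weights, 1 with limma voom, both with the identifier prefix as a random block and with neither block nor weights, 91 with the mitochondrial split as a covariate, 57 in the libraries that express the block and 1 without both first replicates; leaving out 1 library gave 0 to 4. The limma voom call was the same gene with and without the block, ENSOCUG00000002957, with an adjusted p of 0.0376 and 0.0114, and over all settings 1.58e-08 to 0.861, the highest with counts summed per prefix. DESeq2 and the covariate fit shared 38 genes. The quality weights ran from 0.401 to 6.22, the latter for Ad-GFP replicate 3. In OPC, the count of 0 became 7 with DESeq2, 9 with sample quality weights (weight 0.0842 for Ad-PPARg replicate 4), 2 with all 16 libraries in one fit, 1 with the split as a covariate and 47 in the libraries that express the block; leaving out 1 library gave 0 to 2. For the difference of effects it became 2 with DESeq2 and 4 with sample quality weights; leaving out 1 library gave 0 to 1. All other settings kept 0 in these 3 comparisons.

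With the prefix as a random block in limma voom, the unadjusted count was 808 in microglia (correlation 0.534), against 1741 in limma voom with neither block nor weights, and 35 in OPC (correlation 0.809), against 167. With counts summed per prefix, which leaves fewer samples, and fewest in OPC Ad-GFP, edgeR gave 524 against 1488 and 45 against 166. The genes given by identifier kept their direction in every setting run, 23 in microglia and 21 or 22 in OPC. This is no support for them, since they were picked for a low p in these same libraries. The treatments did not overlap in any of them, so leaving out 1 library could hardly reverse a direction. The animal as a fixed replicate block gave 0 genes for the difference of effects (662 with an unadjusted p under 0.05, against 402) and 9860 between the sorts. As a random block in limma voom (correlation 0.103) it gave 0 (466 unadjusted) and 10411, against 0 (394) and 10263 without block or weights. Between the sorts, 10071 genes became 6462 with the added 2-fold threshold, which calls fewer by construction, and 9718 to 10549 with 1 library left out. The 1 class called in microglia and the 4 in OPC each became 0 with an estimated correlation and 0 with fry; leaving out 1 library gave 1 to 3 in microglia (3 without Ad-PPARg replicate 1, 2 without Ad-PPARg replicate 4 or Ad-GFP replicate 1) and 3 to 4 in OPC (3 without Ad-PPARg replicate 2, Ad-PPARg replicate 4 or Ad-GFP replicate 1). The planned gene lists were not run, since no identifier matched a name. At these depths and spreads, edgeR recovered simulated 2-fold changes for 66% of the changed genes in microglia and 26% in OPC. DESeq2 recovered 80% and 53%, with more false calls. Only well-expressed genes were changed in the simulation.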

Other observations

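The tests over other divisions of the adjusted edgeR counts were written after those counts had been seen, and the covariate fit, the classes, the comparison of the sorts and the hypotheses on neighbouring genes and on both cell types were added after seeing the data.

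Genes next to each other were frequent among the lowest p-values in OPC. Among the 200 genes with the lowest p in OPC, 14 adjacent pairs of tested genes were found, on 8 chromosomes or scaffolds, all 14 with both members in the same direction (10 higher after Ad-PPARg) and 1 with overlapping members, where shuffled p-values gave a mean of 2.82 (permutation p = 0.0001, the smallest that 10000 shuffles can give). They included 3 neighbouring pairs in a row on chromosome 12 (23346548 to 23379513) and 2 pairs on scaffold AAGW02081404, which follows the mitochondrial split. In microglia there were 5 such pairs, 4 with both members in the same direction, against a mean of 2.88 (permutation p = 0.162), among them the pair on chromosome 5. Shuffles are not the whole yardstick, since the other divisions of the 8 OPC libraries gave a median of 7 pairs and up to 14, so that 2 of 35 divisions had as many. In microglia 31 of 35 had at least 5, and the highest had 18. Domains of neighbouring genes may thus vary between animals whatever the treatment, and chance cannot be excluded for either cell type.

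The counts were set against other divisions of the 8 libraries of a cell type into 4 and 4. In microglia, 5 of 35 divisions gave at least the 1488 genes with an unadjusted p under 0.05 (highest other 2585), 8 of 35 at least the 100 calls of DESeq2 (highest other 1150) and 4 of 35 at least the 1291 calls with quality weights (highest other 2741), so chance could not be excluded for these. Counts several times the real one may come from a structure of the samples, which was not tested against simulated independent libraries. The 6 other divisions that keep every identifier prefix whole tended to have higher counts than the rest: with DESeq2 a median of 116.5 against 1.5 in the 28 that part a prefix, and with unadjusted p-values 955.5 against 365. With DESeq2, 3 of the 6 and 4 of the 28 reached the real count, and with quality weights 1 of the 6 and 2 of the 28 did. The highest with DESeq2 and with quality weights parted a prefix, so the prefix alone does not account for the highest counts. For the adjusted edgeR count of 0, all 35 divisions are as large by definition, and the highest other was 4; 4 of the 6 and 1 of the 28 had any call. With the mitochondrial split as a covariate, 1 of 35 divisions, the real one, gave as many as 91 genes and the highest other gave 8. Of the others, 4 of the 6 and 0 of the 28 had any call. The 28 are thus a poor yardstick for a treatment that parts no prefix. The real division was the highest of the 7 that keep prefixes whole, too few for a share under 0.05, so chance could not be excluded. That covariate was picked from the data, the prefixes stay tied to treatment, and only 7 divisions keep the prefixes whole, so the 91 genes are at most a lead. For the class call in microglia, 34 of 35 divisions gave at least 1 class (highest other 7).

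In OPC, 28 of 35 divisions gave at least 166 genes with an unadjusted p under 0.05. The highest other, 1883, was several times that count, and a structure of the samples may play a part here too. At least the 7 calls of DESeq2 came in 10 of 35 (highest other 135), at least 9 with quality weights in 5 of 35 (highest other 116), at least 1 with the covariate in 3 of 35 (highest other 9) and at least 4 classes in 11 of 35 (highest other 5). The 2 other divisions that keep prefixes whole gave 1035 and 1883 genes with an unadjusted p under 0.05 (median 331.5 in the 32 that part a prefix) and 20 and 135 with DESeq2 (median 2), and 0 with the covariate; the highest for the quality weights, the covariate and the classes parted a prefix. The adjusted edgeR count of 0 was met by all 35 (highest other 1). For the difference of effects, 100 drawn divisions all met the count of 0 (highest other 1), and 70 of 100 gave at least 402 genes with an unadjusted p under 0.05 (highest other 2969). Chance could be excluded for none of these. Between the sorts, 1 of 100 drawn divisions, the real one, reached 9982 genes in a fit without treatment (highest other 6613). A chance division is thus argued against, for a contrast that the sorting itself set. The drawn divisions took no account of animals that gave both cell types.

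Fold changes of the treatment in microglia and OPC correlated at r = 0.143 across 12413 genes, which are not independent replicates. Over the 6 animals with both cell types the correlation was 0.330, and the other 9 of the 10 divisions of these animals into 3 and 3 gave 0.144 to 0.447. A treatment response common to both cell types beyond what animals share anyway was therefore not seen, and 10 divisions are too few for a share under 0.05.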
